A study of Caenorhabditis elegans with 6 samples.

How the data were processed

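The 6 libraries were made from total RNA of whole N2 hermaphrodites with the TruSeq RNA Library Preparation Kit v2, per the labels' protocols, a kit that does not mark strand. The authors deposited whole-number counts per gene and a second table named RPKM, both with 46748 genes and 1 column per library. Reads were handled with bcl2fastq 1.8.4, STAR 2.4.1d and featureCounts 1.4.6-p4 on genome WBcel235, per the submitters' processing notes. The options, the annotation release and the step from counts to RPKM are not given in the sources used here. The design fixed in advance took the second table for RPKM, but its values were treated as a score rather than as the deposited RPKM, because the factor between count and value changed along the table with a period of 36 genes. The test on those values was kept as an alternative set in advance, limma on log2(value + 1) or log2(value + 0.1) with a minimum mean of 0.5 or no minimum. A fold change on that scale understates the change of low genes.

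Groups came from the perturbation named in the labels, and replicate numbers follow accession order and only name a library. Depth was 26125982 to 40726259 counts per library. Counts differed by a chi-square per gene of 18.8 to 31.4 between libraries of the same group and of 7.13 to 53.3 across groups, so no library was a copy of another. The labels number the libraries 13, 17 and 21 (L4440) and 14, 18 and 22 (T25B9.1 RNAi) and do not say that consecutive numbers share anything, so the comparison was fitted without a block and the block of consecutive numbers was an alternative. By that chi-square 17 and 18 (7.13) and 21 and 22 (11.1) were the closest pairs of libraries, while 13 and 14 (53.3) were the farthest apart.

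Genes were filtered with filterByExpr, which kept 13374 of the 22665 genes with at least 1 count. Counts were scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3), 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common dispersion was 0.0165, a biological coefficient of variation of 12.8%. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM are TMM-scaled and given as mean ± SD of 3 libraries. An exact permutation test of 3 against 3 cannot give a p under 0.1, so no such test was used for single genes.

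The 35 gene lists were fixed before the data were examined, as was the set of alternatives tried first, and T25B9.1 was left out of every list. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, 2-sided and adjusted over the 35 lists, and again with a correlation estimated per list and with fry. With an estimated correlation camera called 0 of the 35 lists, against 10 with the preset one, and fry called 0. The named genes are T25B9.1, up to 12 genes per direction with an adjusted p under 0.05, at least 1 CPM in the higher group and groups that do not overlap, and in each list up to 4 tested members with the smallest p. The threshold part of that rule named 0 genes. Names were matched by identifier, with 43693 identifiers matched to a symbol and 46449 found in the Ensembl annotation, release 115, of the same build, 19641 of them protein coding. The listed names hsp-16.11, hsp-16.49, sodh-1, drh-2, ram-4 and bus-8 were not matched. Near-identical family members, such as the yolk protein, collagen and heat shock genes, and genes that overlap on opposite strands can share reads, and their counts are uncertain to that extent.

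The alternatives were RLE, upper quartile or no composition factors, DESeq2 1.42.0, limma-voom, the likelihood ratio test of edgeR, no filter, a stricter filter of 1 CPM and 10 counts in 3 libraries, the deposited RPKM, each library left out in turn, and the block. A lowess correction for exonic length per library (span 0.3, for the 13281 tested genes with a length), the same with the block, and camera with an estimated correlation under the block or without T25B9.1 RNAi replicate 1 were added after the data were seen. For DESeq2, lists were tested with camera's form for ranked statistics, on its log2 fold changes divided by their SE, at the preset correlation. That test ran over genes without the filter, so list calls with DESeq2 differ in statistic and background genes as well as in model. GC content was not examined, since no genome sequence was used here.

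The test was checked on counts simulated from the means and library sizes of this comparison, with 200 genes changed. The quasi-likelihood test recovered 49.5% of genes changed 1.5-fold among 13222 tested, 65% at 2-fold among 13250 and 94% at 4-fold among 13215, with 7, 13 and 24 false calls. DESeq2 recovered 56.5%, 67.5% and 90.5% with 27, 28 and 37 false calls. At each fold the false calls made up a share over 0.05 of all calls by either test, and a larger share by DESeq2. Neither test therefore held its threshold in this simulation. Each gene was simulated independently, without the spread that genes share between the real libraries, so these shares need not hold for the real counts. In those, T25B9.1 was 3.58-fold lower and had an adjusted p = 0.0525 in the quasi-likelihood test. Of 40 simulated unchanged lists 0 were called by camera, in genes simulated without correlation. The deposited counts have no molecular identifiers, so reads that are copies of 1 molecule are not told apart. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.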

Results

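RNA from whole Caenorhabditis elegans hermaphrodites of the wild-type laboratory strain N2 was sequenced at an age of 2 days, which the series title counts from the last larval stage. The worms had been treated with RNA interference (RNAi) against the gene T25B9.1 or with L4440, the empty vector used as the control in RNAi by feeding. T25B9.1 is the worm counterpart of glycine C-acetyltransferase, the mitochondrial enzyme that completes the breakdown of threonine to glycine by way of threonine dehydrogenase. The comparison asks which transcripts differed when this enzyme was knocked down. There were 3 libraries per group, and samples of 5 days, which the title mentions, were not analysed here. The L4440 libraries held 27981613, 31850495 and 28596696 counts in replicates 1, 2 and 3, and the T25B9.1 RNAi libraries held 26125982, 28971466 and 40726259. At least 1 count was present for 18279 to 19457 genes per library. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

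T25B9.1 itself was lower in all 3 RNAi libraries than in any control library. Its level was 5.79 ± 0.721 CPM (counts scaled to a common library size; SD, n = 3) with L4440 and 1.61 ± 0.222 CPM (SD, n = 3) with T25B9.1 RNAi, a 3.58-fold difference. The gene (WBGene00012007) is protein coding and lies on the minus strand of chromosome IV from 10748378 to 10750141 in build WBcel235, with 5 exons and 1285 exonic bases. The deposited counts were 166, 154 and 185 in the L4440 libraries and 36, 49 and 73 in the RNAi libraries. The log2 fold change was -1.84 with an SE of 0.184. As the target fixed in advance, T25B9.1 had an unadjusted p = 3.92e-06 in edgeR's quasi-likelihood test, the smallest of all genes tested. Adjusted over the 13374 genes tested, edgeR gave an adjusted p = 0.0525, and the alternatives on the counts ranged from 1.29e-11 by DESeq2 to 0.307 without L4440 replicate 1. The last 24 exonic bases are shared with T25B9.3 on the opposite strand, which stood at 0.659 ± 0.105 CPM with L4440 and 0.775 ± 0.279 CPM with RNAi (SD, n = 3).

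**Figure D1:**
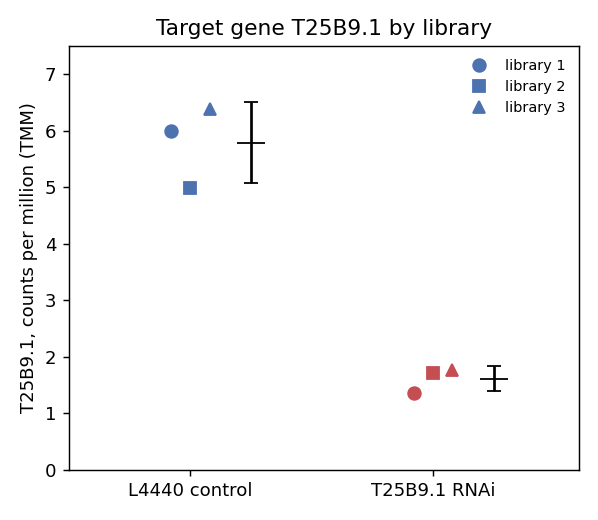
Level of T25B9.1 in each library, in CPM after TMM scaling, by group, with each point 1 library and each bar the mean and SD of 3 libraries beside the points. The RNAi mean of 1.61 CPM lies below the L4440 mean of 5.79 CPM, with no overlap between the groups.

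Outside the target, 6 of the genes that DESeq2 called are given here with their values. R08F11.4 was at 2.16 ± 0.723 CPM with L4440 and 9.65 ± 2.55 CPM with RNAi (SD, n = 3), a log2 fold change of 2.16 (SE 0.276). C14C6.5 was at 19.3 ± 0.938 and 40.7 ± 8.89 CPM. The arginine kinase gene argk-1, whose product buffers ATP, was at 24.7 ± 3.02 and 43.9 ± 5.52 CPM. The gene cth-1, which encodes a cystathionine gamma-lyase of cysteine synthesis, was at 62.9 ± 3.00 and 84.1 ± 4.45 CPM, and it lies directly beside argk-1 on chromosome V. In the other direction, rips-1 was at 36.8 ± 3.51 and 25.1 ± 1.6 CPM, and the metallothionein gene mtl-2, which binds metals in the intestine, was at 44.4 ± 5.81 and 31.6 ± 2.00 CPM. The genes R08F11.4, C14C6.5, argk-1 and rips-1 were chosen after their values were seen, while cth-1 and mtl-2 were named by the rule fixed in advance.

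None of these genes passed the threshold of edgeR's quasi-likelihood test, which called 0 genes higher and 0 genes lower among 13374 at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 826 genes, 536 higher and 290 lower, where chance gives 669. DESeq2 called 14 genes, 10 higher and 4 lower. They were T25B9.1 and the 6 genes above, together with srlf-3, F01D5.5, pqn-36, lys-7, wrt-2 and K06A9.1 (higher) and pud-3 (lower). The likelihood ratio test of edgeR called 12 genes, 10 of them shared with DESeq2, and limma-voom called 0 genes with 710 at an unadjusted p under 0.05. The 3 libraries of 1 group lay beyond all 3 of the other for 1452 genes (10.9%), where chance gives 10%.

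**Figure D2:**
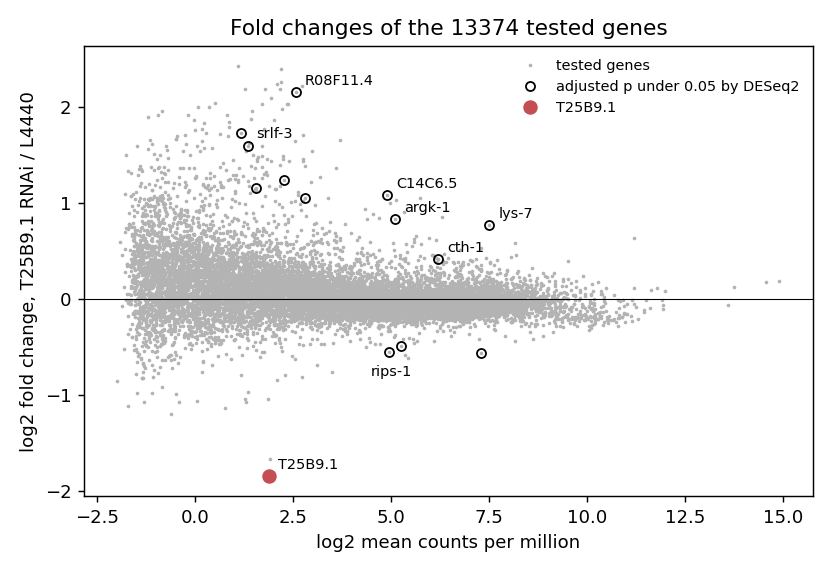
Log2 fold change of T25B9.1 RNAi over L4440 for the 13374 genes tested, against the log2 of their mean CPM. Open circles mark the 14 genes with an adjusted p under 0.05 by DESeq2, and the filled circle marks T25B9.1 at a log2 fold change of -1.84.

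Of 35 gene lists fixed before the data were examined, 7 were lower and 3 higher under T25B9.1 RNAi by camera with its preset correlation of 0.01. None of the 35 was called when the correlation was estimated (lowest adjusted p = 0.676 with an estimated correlation). The 81 cytosolic ribosomal protein genes were lower, with 79 log2 fold changes below 0 and a median of -0.20. Of these, 35 had an unadjusted p under 0.05, all lower, and 0 passed when adjusted over the list alone. Examples of the 35 were rpl-26, at 692 ± 29.1 CPM with L4440 and 571 ± 35 CPM with RNAi (SD, n = 3), and rps-29, at 403 ± 24.3 and 332 ± 28.4 CPM. The median of the list, taken in each library against the L4440 mean, was -0.203 ± 0.078 in the RNAi libraries and 0.001 ± 0.11 in the L4440 libraries (SD, n = 3), with no overlap. The camera adjusted p was 5.27e-38, and the adjusted p = 0.676 with an estimated correlation, which was 0.659 for this list. In the length correction, added after the data were seen, its median was -0.129 (camera adjusted p = 4.52e-22).

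The 33 proteasome genes, which encode the subunits of the main protein-degrading complex of the cytosol, had 32 log2 fold changes below 0 and a median of -0.10 (camera adjusted p = 6.17e-07). The subunit gene pbs-1 was at 291 ± 12.2 CPM with L4440 and 246 ± 24.3 CPM with RNAi. The 34 nuclear genes of the mitochondrial respiratory chain had 31 below 0 and a median of -0.10 (camera adjusted p = 4.88e-07). The cytochrome c oxidase gene cox-7C was at 144 ± 9.61 and 117 ± 7.83 CPM, and mev-1, a subunit of succinate dehydrogenase, at 90.4 ± 2.31 and 78.6 ± 4.07 CPM. Both lists had an adjusted p = 0.676 with an estimated correlation. Of the proteasome genes 1 and of the respiratory chain genes 4 had an unadjusted p under 0.05, all lower, and 0 passed when adjusted over the list alone. The proteasome median was -0.065 without L4440 replicate 1 or T25B9.1 RNAi replicate 1 and -0.193 without T25B9.1 RNAi replicate 2, and the respiratory chain median was -0.053 without L4440 replicate 1, with the call kept each time.

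The 4 remaining lists that were lower each had an adjusted p = 0.676 with an estimated correlation. Of 21 antioxidant enzyme genes 14 were below 0 (median -0.10, camera adjusted p = 0.0333). Among them sod-1, the cytosolic superoxide dismutase, was at 180 ± 9.76 CPM with L4440 and 155 ± 8.77 CPM with RNAi. Of 18 glycolysis genes 15 were below 0 (median -0.057, camera adjusted p = 0.0333), as for pgk-1 at 177 ± 11.5 and 158 ± 12.4 CPM. Of 33 innate immune effector genes 24 were below 0 (median -0.11, camera adjusted p = 0.0333). In that list the lysozyme gene lys-7 went the other way, at 135 ± 21.2 and 231 ± 62.5 CPM, while lys-2 was at 197 ± 23.1 and 162 ± 21.9 CPM. Of 28 oogenesis and eggshell genes 20 were below 0 (median -0.072, camera adjusted p = 0.0246), as for puf-5, an RNA-binding regulator of oocytes, at 1188 ± 21.5 and 1092 ± 97.7 CPM. Without T25B9.1 RNAi replicate 1 the antioxidant (median -0.047), immune (-0.008) and oogenesis (-0.039) lists were not called, nor were the antioxidant list without L4440 replicate 1, the oogenesis list without L4440 replicate 2, the immune list without L4440 replicate 3 (-0.045) or T25B9.1 RNAi replicate 2, and the glycolysis list without L4440 replicate 1 (-0.025) or 2 or T25B9.1 RNAi replicate 3 (-0.028). On the counts, the oogenesis call was also lost with library totals only (adjusted p = 0.0508), upper quartile factors (0.0523) and the stricter filter (0.0561), the glycolysis call with upper quartile factors (0.0523) and the stricter filter (0.0735), the antioxidant call with the stricter filter (0.0561), and the immune call with limma-voom (0.0568) and the stricter filter (0.0561). On the deposited RPKM the oogenesis, glycolysis and antioxidant lists were not called, and the immune list was not called without the filter (camera adjusted p = 0.0546). In the length correction, added after the data were seen, camera did not call the antioxidant (-0.068, adjusted p = 0.192) and immune (-0.071, 0.149) lists. With the call kept, the medians were up to 2.53 times as large, as for the immune list without T25B9.1 RNAi replicate 3 (-0.278), and 0.66 times as large for the antioxidant list without L4440 replicate 2 (-0.066).

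The moulting, pharynx and neuron lists were higher. For moulting and pharynx the adjusted p = 0.676 with an estimated correlation, and for neurons the adjusted p = 0.806 with an estimated correlation. Of 15 moulting genes, which act when the cuticle is shed and remade, 14 were above 0 with a median of 0.46 (camera adjusted p = 4.2e-07). The protease inhibitor gene mlt-11 was at 34.7 ± 7.44 CPM with L4440 and 72.1 ± 43.2 CPM with RNAi, and qua-1, a hedgehog-related gene, at 2.00 ± 0.453 and 8.27 ± 9.44 CPM. Of 15 pharynx genes 14 were above 0 with a median of 0.52 (camera adjusted p = 5.11e-05), and the pharyngeal myosin gene myo-2 was at 23.1 ± 7.65 and 47.2 ± 30 CPM. Of 53 neuron genes 37 were above 0 with a median of 0.14 (camera adjusted p = 0.0333), and unc-31, needed for release of neuropeptides, was at 2.51 ± 0.161 and 3.99 ± 0.942 CPM. At an unadjusted p under 0.05 there were 7 moulting, 5 pharynx and 5 neuron genes, all higher, and 1 neuron gene lower.

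T25B9.1 RNAi replicate 1 stood apart from the other libraries along with these lists. On the first principal component, with 47.1% of the variance, it lay at 41.9 while the other 5 libraries lay between -27.5 and 4.6. Its moulting median was 0.93 above the L4440 mean, against 0.22 and 0.21 in RNAi replicates 2 and 3 and 0.21 in L4440 replicate 1. Its pharynx median was 0.91, against -0.001 and 0.25 in RNAi replicates 2 and 3, which lay below the 0.44 of L4440 replicate 3. Without T25B9.1 RNAi replicate 1 the median was 0.16 for moulting, 0.14 for pharynx and -0.009 for neurons, and camera no longer called the neuron list. The neuron list also lost its call without L4440 replicate 2 (median 0.018), with library totals only (adjusted p = 0.0508), upper quartile factors (0.0523) and the stricter filter (0.0561), and on the deposited RPKM with either pseudocount (0.428 and 0.361) but not without its filter, and the pharynx median was 0.85 without L4440 replicate 3. In the length correction, added after the data were seen, the moulting median was 0.301 (camera adjusted p = 8.53e-06).

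**Figure D3:**
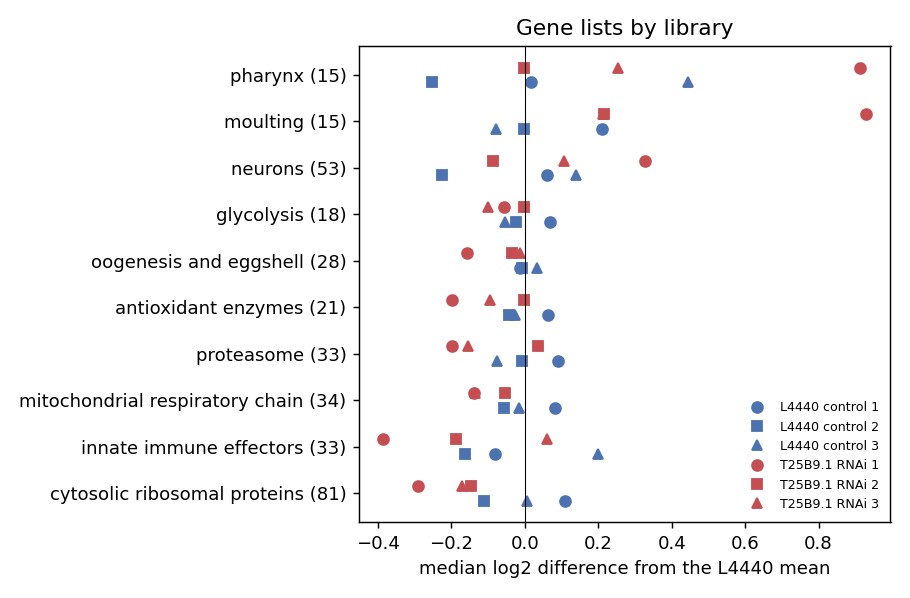
Median log2 difference from the L4440 mean in each library, over the tested genes of each of the 10 lists called by camera with a preset correlation, with the number of genes in brackets. Points are single libraries, in blue for L4440 and red for T25B9.1 RNAi, and some overlap: the moulting points of RNAi replicates 2 and 3 (0.22 and 0.21) and the respiratory chain points of RNAi replicates 1 and 3 (-0.14 each). RNAi replicate 1 has the highest moulting and pharynx medians, at 0.93 and 0.91.

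The lists nearest to the knocked-down enzyme were not called by camera. Of 16 threonine, glycine and serine metabolism genes other than the target, 12 were below 0 (median -0.072, camera adjusted p = 0.32). The gene cth-1, with a log2 fold change of 0.42 (SE 0.069, edgeR adjusted p = 0.429 over all genes), was the 1 gene of the list that passed when adjusted over the list alone. The threonine dehydrogenase gene F08F3.4, which acts just before T25B9.1, was at 41.1 ± 6.67 CPM with L4440 and 39.8 ± 2.85 CPM with RNAi. Of 12 genes that detoxify methylglyoxal, a reactive by-product of threonine and sugar breakdown, 9 were below 0 (median -0.086, camera adjusted p = 0.255). The glyoxalase gene glod-4 was at 45.8 ± 2.27 and 42.9 ± 3.01 CPM, and the predicted reductase gene ZC443.1 at 1.74 ± 0.2 and 2.62 ± 0.156 CPM. With 1 library left out the threonine list median ran from -0.015 (without L4440 replicate 1) to -0.135 (without T25B9.1 RNAi replicate 2), and the methylglyoxal median from -0.044 to -0.14 without the same libraries. By fry's either-direction test the unadjusted p was 0.00532 for the threonine list and 0.0136 for the methylglyoxal list, and adjusted over the 35 lists, a step added after the data were seen, it was 0.186 and 0.238. That test gave 4 of the 35 lists an unadjusted p under 0.05, among them also the UDP-glucuronosyltransferase (0.0243) and intestine (0.0354) lists, and 0 an adjusted p under 0.05. The methionine and propionate list had a median of -0.005 over 17 genes (camera adjusted p = 0.902), from -0.06 without L4440 replicate 3 to 0.049 without T25B9.1 RNAi replicate 3. The lists of fatty acid synthesis (17 genes, median -0.028) and of fatty acid oxidation with lysosomal lipases (23 genes, median -0.057) had camera adjusted p of 0.346 and 0.0627. The fatty acid oxidation list was called lower with the block of consecutive library numbers (-0.058, camera adjusted p = 0.0142, adjusted p = 0.834 with an estimated correlation), without L4440 replicate 3 (0.0023), without T25B9.1 RNAi replicate 2 (0.00469), with DESeq2 (0.0121) and with no filter (0.0108), and had an adjusted p = 0.676 with an estimated correlation and no block. The fatty acid synthesis median ran from -0.004 without T25B9.1 RNAi replicate 1 to -0.091 without T25B9.1 RNAi replicate 3. The genes F08F3.4 and glod-4 were named for their place in the pathway after the data were seen.

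Apart from the antioxidant and immune lists above, stress and protein-folding lists were not called by camera in edgeR's fit of all 6 libraries without a block. That fit used TMM scaling and the filter. The median was -0.071 over 17 cytosolic heat shock and chaperone genes (camera adjusted p = 0.0625), -0.04 over 8 chaperonin genes (0.346), -0.027 over 17 genes of folding in the endoplasmic reticulum (0.384) and 0.029 over 12 genes of mitochondrial folding (0.73), the last from -0.043 without T25B9.1 RNAi replicate 2 to 0.077 without T25B9.1 RNAi replicate 3. The mitochondrial chaperone gene hsp-6 was at 726 ± 89.7 CPM with L4440 and 817 ± 108 CPM with RNAi. For targets of the stress regulator SKN-1 the median was -0.11 over 18 genes (camera adjusted p = 0.0892), with gst-4 at 21.3 ± 5.13 and 15.9 ± 3.41 CPM. Genes induced by the insulin-pathway regulator DAF-16 had a median of -0.051 over 15 genes (0.0895), with the metallothionein gene mtl-1 at 14.2 ± 4.83 and 8.40 ± 1.92 CPM. Genes repressed by DAF-16 had a median of 0.094 over 10 genes (0.992), which was -0.15 without T25B9.1 RNAi replicate 3, -0.062 without L4440 replicate 1 and 0.204 without L4440 replicate 3, and 44 autophagy and lysosome genes had a median of -0.015 (0.358). The 20 genes for longevity and stress regulators had 17 above 0 and a median of 0.07 (0.0509). The regulators were called higher with library totals only (0.0249), upper quartile factors (0.0329), DESeq2 (0.0315), limma-voom (0.0371) and the stricter filter (0.0255), and without L4440 replicate 2 (0.124, 0.00256) or T25B9.1 RNAi replicate 3 (0.082, 0.0189), while their median was 0.013 in the length correction. The heat shock list was called lower with library totals only (0.0479), DESeq2 (0.019) and no filter (0.026), and the SKN-1 list with DESeq2 (0.0315) and no filter (0.0438). Without the block the regulators, heat shock, SKN-1 and DAF-16 induced lists each had an adjusted p = 0.676 with an estimated correlation. With the block of consecutive library numbers, for which the labels name no shared culture or batch, camera called the heat shock (adjusted p = 0.0447), SKN-1 (0.0142) and DAF-16 induced (0.039) lists lower and the regulators (0.0447) higher, each with an adjusted p = 0.834 with an estimated correlation. The chaperonin list was called lower without L4440 replicate 3 (-0.175, 0.000721) or T25B9.1 RNAi replicate 2 (-0.218, 0.00272) and had a median of 0.048 without T25B9.1 RNAi replicate 3, and the heat shock list was called lower without the same 2 libraries (-0.119 and -0.171). With all libraries the chaperonin list had an adjusted p = 0.858 with an estimated correlation. Without L4440 replicate 3 the DAF-16 induced list was called lower (-0.125, 0.0019), as was the SKN-1 list without L4440 replicate 2 (-0.161, 0.0133) or T25B9.1 RNAi replicate 3 (-0.117, 0.0462). Neither was called at the smaller medians of -0.063 for SKN-1 without L4440 replicate 1 and -0.026 for heat shock without T25B9.1 RNAi replicate 3.

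Of the detoxification families, the median was -0.049 over 55 cytochrome P450 genes (camera adjusted p = 0.107), -0.031 over 57 UDP-glucuronosyltransferase genes (0.573) and -0.13 over 33 glutathione S-transferase genes (0.0892). The glutathione S-transferase list was called lower with the block (camera adjusted p = 0.022, adjusted p = 0.834 with an estimated correlation) and without L4440 replicate 2 (-0.198, 0.00584) or T25B9.1 RNAi replicate 3 (-0.182, 0.0462), and the cytochrome P450 list without L4440 replicate 3 (-0.063, 0.00965) and with no filter (0.026). Both were called lower with DESeq2 (0.0429 and 0.015), and both had an adjusted p = 0.676 with an estimated correlation. The glutathione S-transferase median was -0.029 without L4440 replicate 3 and -0.078 without T25B9.1 RNAi replicate 1, and the list was called in neither fit. The cytochrome P450 median was -0.017 without T25B9.1 RNAi replicate 3 and -0.024 with the block, and the UDP-glucuronosyltransferase median was 0.004 without L4440 replicate 1. The mean of the UDP-glucuronosyltransferase genes was 0.004 while its median and camera's direction were below 0. In that family ugt-63 was at 11.2 ± 0.591 CPM with L4440 and 15.8 ± 0.608 CPM with RNAi, and it was the 1 gene that passed when adjusted over the list alone. The cytochrome P450 gene cyp-35C1 was at 29.7 ± 3.87 and 24.4 ± 1.53 CPM. The 25 genes of the RNAi machinery had a median of -0.015 (0.889), and it was called lower in the length correction (-0.066, 0.0107) and in that correction with the block (-0.068, 0.0176). In the uncorrected fit it had an adjusted p = 0.934 with an estimated correlation, and its median ran from -0.057 without T25B9.1 RNAi replicate 2 to 0.055 without L4440 replicate 2. The 20 genes of the response to intracellular pathogens had a median of 0.12 (0.384), which was -0.045 without L4440 replicate 1, -0.048 with the stricter filter, 0.014 without T25B9.1 RNAi replicate 3 and 0.026 without T25B9.1 RNAi replicate 1.

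Among tissue and stage lists, the 6 yolk protein genes were all above 0 with a median of 0.12 (camera adjusted p = 0.0892), led by vit-6 at 28930 ± 7010 CPM with L4440 and 32890 ± 2900 CPM with RNAi. The yolk median was 0.301 without L4440 replicate 2 (camera adjusted p = 2.93e-06), 0.016 without L4440 replicate 1 and -0.032 in the length correction. Both the yolk and the collagen list were called higher with DESeq2 (0.0445 and 0.0429), while yolk had an adjusted p = 0.728 with an estimated correlation and collagens an adjusted p = 0.866 with an estimated correlation. The 100 cuticle collagen genes had 59 above 0, a median of 0.29 and a mean of 0.56 (0.157). In that family 9 genes were higher and 10 lower at an unadjusted p under 0.05, such as col-74 at 2.29 ± 0.893 and 5.14 ± 1.63 CPM and col-140 at 450 ± 37 and 338 ± 44.1 CPM. The median was 0.11 over 18 body wall muscle genes (0.106), 0.039 over 19 intestine genes (0.73), 0.042 over 17 embryonic genes (0.743) and -0.16 over 7 sperm genes (0.441). With 1 library left out the sperm median reached 0.007 (without T25B9.1 RNAi replicate 2), the embryonic median ran from -0.04 (without T25B9.1 RNAi replicate 2) to 0.15 (without T25B9.1 RNAi replicate 3), and the intestine median from 0.008 to 0.062. In the intestine list mtl-2 was the 1 gene that passed when adjusted over the list alone, lower with RNAi. Without T25B9.1 RNAi replicate 1, the collagen median was -0.109 and the muscle median -0.112, while without T25B9.1 RNAi replicate 2 both were called higher (0.573 and 0.259), as they were without L4440 replicate 3 (0.462 and 0.238). Camera also called collagens higher without L4440 replicate 1 (0.441, adjusted p = 0.012), with no filter (0.0438) and on the filtered deposited RPKM with either pseudocount (3.39e-07 and 8.78e-07). With all libraries collagens had an adjusted p = 0.866 with an estimated correlation and muscle an adjusted p = 0.815 with an estimated correlation.

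The deposited values named RPKM did not share a scale between libraries, so they were used only in the alternatives set in advance. Over 6876 genes, the ratio of count to deposited value between libraries had an SD of 0.303 on the log2 scale when 1 ratio was assumed for all genes, and of 3.22e-05 when it was allowed to differ by the position of the gene in the table with a period of 36 genes. The value given to 1 count differed between libraries by a factor of 0.576 to 1.74. Library totals, here 26125982 to 40726259 counts, also give such a factor in RPKM, apart from gene length. For a given pair of libraries that factor is the same for all genes. For T25B9.1 the deposited values were 4.93, 3.77 and 4.13 with L4440 and 0.851, 1.17 and 2.17 with RNAi, and the log2 fold change on the log2(value + 1) scale was -1.17.

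**Figure D4:**
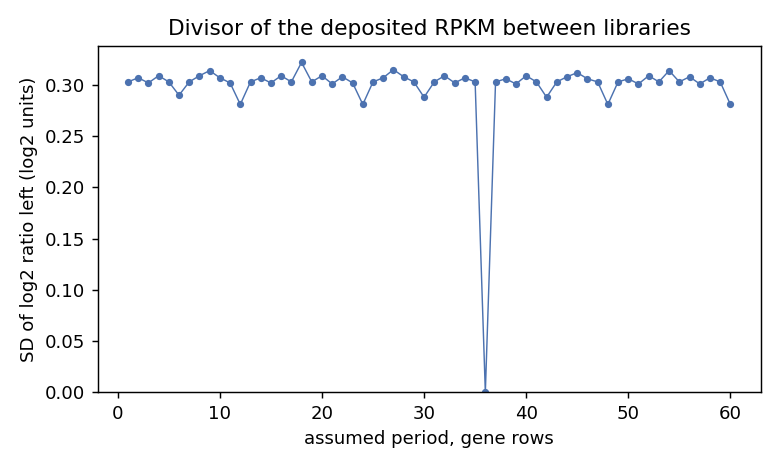
SD of the log2 ratio of count to deposited RPKM between libraries that is left when the ratio may differ with the position of the gene in the table, plotted against the assumed period in genes. The SD is 0.303 at a period of 1 and 3.22e-05 at a period of 36.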

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

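The length correction, the fits that combine it or an estimated correlation with the block, and the estimated correlation without T25B9.1 RNAi replicate 1 were chosen after the result was seen. The log2 fold change of T25B9.1 kept its direction in all alternatives, and its adjusted p passed the threshold with RLE factors (-1.835, p 0.0346), DESeq2 (-1.844), the likelihood ratio test (-1.835), no filter (-1.848), the deposited RPKM with a pseudocount of 1 (-1.169) or 0.1 (-1.635) but not without its filter, the length correction (-1.818, p 0.0243) and that correction with the block (-1.822).

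Genes called higher and lower were 0 and 0 with edgeR's quasi-likelihood test, with 826 at an unadjusted p under 0.05. They were 0 and 1 with RLE factors, 10 and 4 with DESeq2, 9 and 3 with the likelihood ratio test, 64 and 19 or 43 and 15 with the deposited RPKM at a pseudocount of 1 or 0.1, 0 and 1 with the length correction, and 11 and 6 with that correction and the block. Leaving out 1 library gave 0 to 1 higher, the 1 being C14C6.5 without T25B9.1 RNAi replicate 1, and 0 lower. Without a filter there were 123 and 16. Of these 139, 130 also pass the filter, and the prior degrees of freedom were 40.2 against 4.9 with the filter, so the pooled spread and not only the added genes differed. The cause of the other differences was not tested.

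Gene lists called were 10, and 18 with DESeq2, 6 with the stricter filter, 6 to 16 with 1 library left out (6 without T25B9.1 RNAi replicate 1, 16 without L4440 replicate 3) and 16 with the block. They were 0 with an estimated correlation, 0 with fry, 0 with an estimated correlation and the block, and 0 with an estimated correlation without T25B9.1 RNAi replicate 1. On the deposited RPKM, whose scale differed between libraries, the median of all genes moved to 0.11 to 0.129, and the medians of the proteasome (0.005) and respiratory chain (0.002) lists were above 0 while camera called them lower than other genes.

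No paired analysis was possible from replicate numbers because the labels give none. In the check of consecutive library numbers, deviations from the group means correlated at 0.22 to 0.42, against at most 0.10 for other pairs across groups, and 6 of 6 libraries correlated best with the consecutive number, a hint from the data and not the design. With the block edgeR called 0 genes, with 1457 at an unadjusted p under 0.05.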

Other observations

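The tests of lists carried by 1 library, of gene length on the antioxidant and immune lists and on the collagen and pharynx genes of 1 library, of signs and splits by consecutive library numbers, and of the divisor of the deposited RPKM were chosen after the result was seen. The count of lists with separate groups was set before, but it was named a test of spread between libraries only after the result was seen. The cuticle collagen gene rol-6 was at 18.95 CPM in T25B9.1 RNAi replicate 1 and at 0.194 to 3.25 CPM in the other 5 libraries, and sqt-1 at 21.1 CPM against 0.292 to 2.49 CPM. The collagen gene col-19 was at 83.0 CPM in that library and at 85.9 to 113 CPM in the others. These genes were chosen after their values were seen. Over all 100 cuticle collagen genes the library differed from the mean of the other 5 by a median log2 of 0.49, over 53 neuron genes by 0.32 and over 18 body wall muscle genes by 0.46.

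The ribosomal, proteasome, respiratory chain, moulting and pharynx lists may reflect the knockdown, a gene length trend, or the spread between libraries, as may the other 5 of the 10 called lists. After the length correction, which took the correlation of log2 fold change with exonic length across genes from 0.316 to 0.005, 8 of the 10 lists were called the same way, so length alone does not account for those 8 calls by camera with its preset correlation. The antioxidant and immune medians kept 67.9% and 64.3% with adjusted p of 0.192 and 0.149, while the 8 kept 63.4% (ribosomal), 64.9% (moulting) and 67.8% (respiratory chain) to 133.3% (glycolysis), so these 2 lists were not set apart by how much length took, and length stays open for them. The spread between libraries stays open, since the RNAi medians lay beyond all L4440 medians in only 2 of the 10 lists, ribosomal and moulting, and so does a difference carried by 1 library, since in only 4 of the 10 did the median keep over 0.5 of its size in all 6 fits without 1 library (smallest ratio -0.06 for neurons, 0.27 for pharynx, 0.35 for moulting and 0.72 for ribosomal). The 10 splits of the 6 libraries are too few for a share under 0.05, so they cannot exclude chance. At least as many lists as the real 10 were called in 8 of the 10 splits, the real one included, with 19 in the highest other. The number of called lists therefore did not set the real grouping apart. All 10 splits called 0 genes higher and 0 lower (highest other 0).

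In 2 other splits 2111 and 2310 genes had an unadjusted p under 0.05, against 826 in the real one, which points to a structure of the samples. Those splits kept both of the closest pairs together, 17 with 18 and 21 with 22, and parted 13 and 14. The other 4 splits that keep 2 of the 3 consecutive pairs together gave 274 to 517. Each of those kept 13 with 14 and parted 17 and 18 or 21 and 22. The pair of 13 and 14 was the farthest apart by chi-square per gene. By correlation of log2 CPM it was not, at 0.988 against 0.983 for 17 and 14, while 17 with 18 (0.995) and 21 with 22 (0.996) were again the closest. None of those 4 splits kept both of the closest pairs together, so they do not test whether doing so goes with the excess. The 4 splits that part all 3 pairs gave 76 to 826, the highest being the real one. Within the 3 pairs of consecutive numbers the list median differed in the same direction in 4 of the 10 called lists (ribosomal, moulting, immune and oogenesis) and in 6 of the 25 others, which leaves the spread between libraries open as well. With the block of consecutive numbers 16 lists were called.

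Larval or moulting animals are a candidate source of the moulting, collagen and pharynx genes in T25B9.1 RNAi replicate 1, whose moulting genes were 0.87 above the other 5 libraries. Such animals would lower the share of oocyte and yolk transcripts, and over those 34 genes the median was -0.124 (95% bootstrap interval over genes -0.166 to 0.024). Both medians met the criterion written for such animals before the result. The interval extends to 0.024, however, so this does not decide it. The parts went opposite ways, -0.137 (-0.187 to -0.076) for 28 oogenesis genes and 0.243 (0.199 to 0.316) for 6 yolk genes, the latter -0.042 after the length correction. In that library the median was also -0.244 for ribosomal and -0.172 for proteasome genes, while other lists were higher, such as body wall muscle (0.456). A fall of that size was therefore not particular to oocyte genes. A length trend in that library does not account for the pharynx and collagen genes, which kept 110.4% and 92.8% of their medians after the correction, but stays open for the moulting genes, which kept 77% (0.67). An effect of the knockdown that reached only this library was not tested.

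A recycled list of library totals may underlie the deposited RPKM. The ratio of count to value between libraries had no spread once allowed to vary with a period of 36 genes, more than the 6 libraries analysed here. The log2 fold between groups was thereby offset by -0.246 to 0.356 depending on the position of the gene, with an SD of 0.145, and by over 1.2-fold for 13.3% of the genes compared. This pattern has no biological counterpart in the design.

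As hypotheses of another kind, cth-1 and rips-1 might belong to a change of cysteine and hydrogen sulfide genes as a group. The other 16 genes of that group had a median log2 fold change of -0.07 (95% bootstrap interval over genes -0.13 to 0.014). They gave no sign of a shift in 1 direction larger than that interval. The interval does not measure the spread between libraries, and it includes the median of the called proteasome list (-0.10). A small shift of the group therefore stays open. Since cth-1 was higher and rips-1 lower, the median of the 16 genes does not speak to changes in both directions. For these fry's either-direction p was 0.427, which does not decide it: the proteasome list, with 32 of 33 genes lower, had 0.27. Of the 16 genes 1 had an unadjusted p under 0.05 in edgeR's test. It was cysl-2, at 78.2 ± 17.6 CPM with L4440 and 57.7 ± 8.91 CPM with RNAi. Of the 13 genes other than the target that DESeq2 called, 8 lie on chromosome V (Fisher's exact p = 0.000814, with the pattern seen before the test). A chromosome V difference between the worm populations could give this, but the share on V among the other 812 genes at an unadjusted p under 0.05 was 19%, 1.01 times that of the remaining genes (18.8%, Fisher's exact p = 0.889). That share speaks to a difference across the whole chromosome and not to one in a short region. It does so only weakly, since chance alone gives 669 genes at that threshold, which would dilute an excess on V. Some of the 8 genes lie close together: lys-7, rips-1 and R08F11.4 between 3481432 and 3805527, and cth-1 beside argk-1. Fisher's test takes genes as independent, which such neighbours may not be.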
